A study of Homo sapiens with 12 samples.

How the data were processed

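The samples were 12 arrays of Caco-2, an established human colorectal cancer cell line, in 4 groups of 3: a control line and a line labelled as carrying an inducible short hairpin RNA (shRNA) against LRH-1, the nuclear receptor encoded by NR5A2, each without doxycycline or 96 hours after addition of 5 µg/ml doxycycline. Titles call the control line native while another label calls it a vector control with a non-silencing sequence. The labels do not settle which of these it was. The design text speaks of separate hairpin sequences, and the labels do not say which was used on the arrays. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

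Biotin-labelled cRNA was hybridised to Illumina bead arrays, per the labels' protocols. The deposited non-normalized table gives a mean bead intensity per probe and array on a linear scale, per the file headers. The same deposited table gives a detection p-value for each probe and array, per the file headers. GenomeStudio and lumi are named, per the submitters' processing notes, with neither role nor version. The deposited value table holds values on a scale close to log2 that the authors brought to the same distribution on every array, as read from the values, with a median of 6.64 in each column. Its background step and its exact transformation are not given in the sources used here, so it served only as an alternative. Each of the 12 arrays correlated best with its own column of that table. No pair of arrays held identical values. All 12 arrays shared 1 chip, per the labels, so no chip term was needed or possible.

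Intensities were background-corrected with the normal-exponential model of limma 3.58.1 in R 4.3.3, which inferred the negative controls from the detection p-values, with an offset of 16. They were then taken to log2 and quantile-normalized. The table held 47314 probes, of which 30109 had 1 gene symbol in the platform annotation, 8 had several and 17197 had none. Symbols were checked through Entrez identifiers against a RefSeq gene table, where 30070 matched and 39 kept the platform symbol. A probe was kept if its detection p-value was under 0.05 on at least 3 of the 12 arrays, which left 22417 probes. Of these, 5682 had no single symbol and entered no gene count. The brightest kept probe stood for its gene, giving 12566 genes, 3311 of which had further kept probes. No genomic coordinates were used here. Probes of near-identical family members can cross-hybridise, so values of such probes are uncertain. Examples are CEACAM, GSTA, UGT2B, UGT1A, AKR1C, metallothionein, SNAR, HBA, PRSS and keratin pseudogene probes.

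A means model over all 12 arrays was fitted with limma's lmFit and eBayes, so that the groups shared an estimate of the spread, and 5 contrasts were tested: doxycycline in each line, the difference of these responses, and the lines against each other with and without doxycycline. All adjusted p-values of genes are limma's, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 34 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 170 tests, and again with an estimated correlation, with which none of the 45 list calls held. Medians of lists are on the log2 scale, and counts of list members are also given adjusted over the list alone.

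Named genes followed a fixed rule. They were NR5A2, and the 10 largest changes each way in the doxycycline comparisons and the 6 largest each way in the line comparisons, among genes past the threshold whose replicates did not overlap (past the threshold alone for the difference of responses). For gene lists they were the 2 to 4 members with the smallest adjusted p, or every member where 4 or fewer passed. Symbols of uncharacterised loci and Y-linked genes were left out. Members named outside the rule are said in the text to have been chosen after their values were seen. Where a probe was undetected on every array of a group, the fold is a bound, the brighter group's mean over the mean of the higher of the dim signal and the lowest detected signal per array, and no size is given for such a gene among the named differences of responses.

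The groups, the model, the gene lists, the named-gene rule and the alternatives were chosen before the data were examined, except that gene lists with no background correction, normexp or median scaling and without single arrays were added afterwards. Alternatives were other background corrections, median scaling, the authors' values, other detection filters, the mean of all probes of a gene, fits of the compared groups alone, the replicate number as a block, array weights, trended robust variance, a fold limit of 1.5, and leaving out each array. The fit and the list tests were run on simulated log2 values for the doxycycline comparison of the shRNA-labelled line over 12566 genes. Background correction and normalization were not part of this. The fit recovered 18 of 50 genes changed by 0.5 on the log2 scale, 45 of 50 changed by 1, and all 50 changed by 1.5 and all 50 changed by 2, with 10 false calls among 173. Camera recovered 20 of 20 lists with every member shifted by 0.5 and called 0 of 200 unshifted lists, in simulations in which genes were independent. The estimated correlation gave the same counts there, so the simulation does not bear on the list calls that were lost with it. Arrays have no sequencing depth: their number, 3 per group, limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.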

Results

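Gene expression was measured on 12 bead arrays of Caco-2 cells, a human colorectal cancer line that can take on features of absorptive intestinal cells. The 4 groups of 3 arrays were a control line and a line labelled as carrying a doxycycline-inducible shRNA against LRH-1 (NR5A2), each without doxycycline or 96 hours after 5 µg/ml of it. Median signals per array lay between 251 and 386 intensity units, and between 41.2% and 44.7% of probes were detected. Replicates correlated at 0.987 to 0.993 across genes. The first principal component, with 37.8% of the variance, separated the lines, and the second, with 24.7%, separated doxycycline from no doxycycline.

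NR5A2, the gene the hairpin was made to silence, was higher with doxycycline in both lines, against the label. On probe ILMN_1811303 its log2 signal in the control line was 10.16 ± 0.09 (SD, n = 3) without doxycycline and 11.05 ± 0.11 (SD, n = 3) with it. In the shRNA-labelled line it was 10.17 ± 0.07 (SD, n = 3) without and 10.67 ± 0.14 (SD, n = 3) with doxycycline. The rise was 0.50 (log2, SE 0.11, adjusted p = 0.00995), or 1.42-fold, in the shRNA-labelled line and 0.89 (SE 0.11, adjusted p = 0.000384), or 1.85-fold, in the control line. The responses differed by -0.39 (95% interval -0.73 to -0.04), which did not pass adjustment (adjusted p = 0.231). With doxycycline, NR5A2 was 0.38 lower on the log2 scale in the shRNA-labelled line, a change of -23.2% (adjusted p = 0.0216), and without it the lines differed by 0.00 (SE 0.11). On probe ILMN_2366654 the lines differed by -0.27 with doxycycline, which did not pass (adjusted p = 0.172), and by -0.18 already without it. Probe ILMN_2366654 gave rises of 0.50 in the shRNA-labelled line and 0.59 in the control line, with a difference of responses of -0.09 (SE 0.18). Probe ILMN_1688932 was not detected on any array. An exact two-sided permutation test of 3 against 3 arrays gave p = 0.1 for each rise, the smallest p it allows. With median scaling the rise in the shRNA-labelled line was 0.40 and no longer passed (adjusted p = 0.254, against 0.00355 to 0.0399 under the other alternatives). The lower NR5A2 of the shRNA-labelled line with doxycycline also failed to pass with median scaling (adjusted p = 0.169), in a fit of these groups alone (0.0657), and without replicate 1 of the control line (0.0819) or replicate 1 (0.0816) or 2 (0.0741) of the shRNA-labelled line with doxycycline. Since the arrays labelled as silenced did not have less NR5A2 than the same line without doxycycline, no direction below is tied to a loss of LRH-1.

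**Figure D1:**
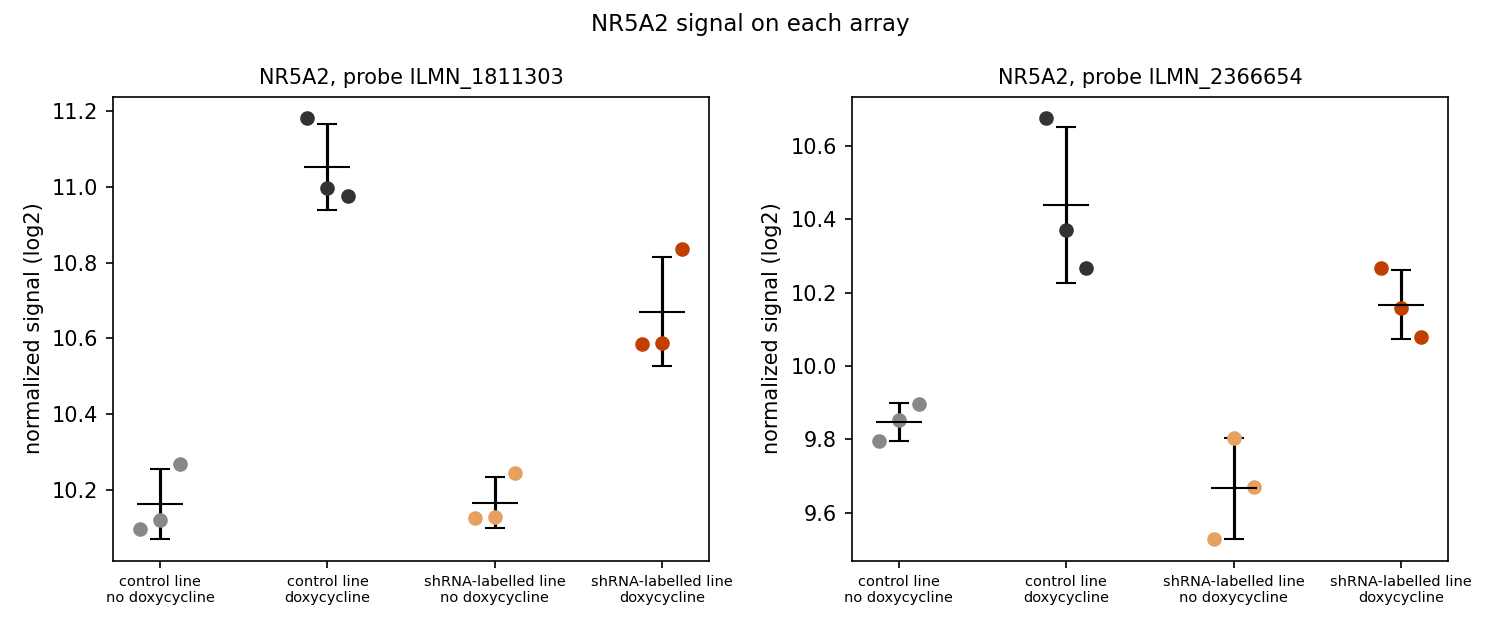
Normalized log2 signal of both detected NR5A2 probes, with a point per array and the mean and SD of the 3 arrays of each group as bars (the axes do not start at 0). On probe ILMN_1811303 the means with doxycycline, 11.05 in the control line and 10.67 in the shRNA-labelled line, lie above those without, 10.16 and 10.17.

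The first comparison asked which genes changed when doxycycline was given to the shRNA-labelled line. ANXA1, a phospholipid-binding annexin, rose 7.88-fold (log2 2.98, SE 0.33, adjusted p = 0.000234), and CEACAM5, carcinoembryonic antigen, rose 7.18-fold (log2 2.84, SE 0.25, adjusted p = 7.05e-05). MYBPH, a myosin-binding protein, fell by 2.32 on the log2 scale (SE 0.34, adjusted p = 0.00126), and G0S2, an inhibitor of lipolysis, fell by 2.04 (SE 0.14, adjusted p = 4.82e-05). In all, 1445 of 12566 genes changed, 815 higher and 630 lower, of which 315 changed at least 2-fold. The excess of rises depended on the processing, with 384 higher and 403 lower under median scaling and 1288 higher and 1410 lower with array weights.

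Among the other largest rises, SKAP1, a signalling adaptor, rose by 2.81 and FCER1G, a chain shared by Fc receptors, by 2.62 on the log2 scale. The amino acid transporter SLC6A20 rose by 2.49, the intestinal keratin KRT20 by 2.42 and the urokinase receptor PLAUR by 2.34. SLC6A20 and KRT20 were each detected on 2 of the 3 arrays without doxycycline. The matrix metalloproteinase MMP10 was at least 4.28-fold higher, S100A3 at least 2.49-fold and the smooth muscle actin ACTG2 at least 2.75-fold, each undetected without doxycycline. Among the falls, BFSP1 fell by 1.96, the dynein DNAH2 by 1.96, PAGE4 by 1.83, the tubulin TUBB1 by 1.81 and urotensin, UTS2, by 1.73. LOX, a collagen cross-linking enzyme, fell by 1.64, CYP4X1 by 1.60 and PRUNE2 by 1.54. With doxycycline BFSP1 was detected on 1 of the 3 arrays, and MYBPH, G0S2, DNAH2 and LOX on 2 of the 3.

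Some genes of cell division and of liver-type secretion fell in this line. Of 30 DNA replication genes, 12 fell, 22 adjusted over the list alone, among them GINS2 (-0.70), RFC2 (-0.55) and CDC45 (-0.55). The list's median was -0.36 (camera adjusted p = 5.79e-09, adjusted p = 0.129 with an estimated correlation). Of 31 mitosis genes, 7 fell, 12 adjusted over the list alone, led by BIRC5 (-0.46), CENPE (-0.45) and KIF20A (-0.53), with a median of -0.28 (camera adjusted p = 1.80e-06, adjusted p = 0.167 with an estimated correlation). Of 14 hepatocyte genes, 7 fell, 9 adjusted over the list alone, including APOH (-1.07), the iron carrier TF, at least 2.01-fold lower, and haptoglobin, HP, at least 1.52-fold lower, both undetected with doxycycline. The hepatocyte median was -0.48 (camera adjusted p = 6.15e-06, adjusted p = 0.219 with an estimated correlation). Of 32 integrated stress response and ATF4 target genes, 7 fell, against 10 lower and 2 higher adjusted over the list alone, led by the asparagine synthetase ASNS (-0.93), STC2 (-0.68) and PSAT1 (-0.62), with a median of -0.23 (adjusted p = 0.198 with an estimated correlation). Of 19 cholesterol synthesis genes, INSIG1 (-0.47) fell, and 11 fell adjusted over the list alone, with a median of -0.36 (adjusted p = 0.167 with an estimated correlation). Of 17 Wnt target genes, 5 fell and CD44 (0.86) rose, against 7 and 1 adjusted over the list alone. The falls included NKD1 (-1.02), TNFRSF19 (-0.56) and ASCL2 (-0.52), with a median of -0.11 (adjusted p = 0.266 with an estimated correlation).

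Some genes of antimicrobial, matrix and inflammatory products rose in the same line. Of 5 Paneth cell genes, 4 rose, also 4 adjusted over the list alone: lysozyme, LYZ (1.64), MMP7, at least 1.84-fold and undetected without doxycycline, ITLN2 (0.97), and PLA2G2A (0.86), detected on 1 of the 3 arrays without it. Their list had a median of 0.97 (camera adjusted p = 0.000139, adjusted p = 0.129 with an estimated correlation). It has 9 members, of which only these 5 were tested. In the control line 2 of the 5 rose, with a median of 0.86 and no list call (camera adjusted p = 0.0864). The list's difference of responses was not called either (camera adjusted p = 0.087). Of 11 epithelial-mesenchymal and matrix genes, 5 rose, including MMP1 (2.09), TIMP2 (0.60) and MMP7, and CDH2, chosen after its value was seen, fell at least 1.04-fold, detected on 2 of the 3 arrays without doxycycline and on none with it. The counts adjusted over the list alone were also 5 and 1, and the median was 0.38 (adjusted p = 0.207 with an estimated correlation). The control line had 2 of these 11 genes higher, with a median of 0.16 and no list call (camera adjusted p = 0.399). This list's difference of responses was not called either (camera adjusted p = 0.0978). Of 16 NF-kB and inflammatory genes, 5 rose, also 5 adjusted over the list alone, led by PTGS2 (1.17), NFKB2 (1.59) and RELB (0.92), with a median of 0.18 (adjusted p = 0.155 with an estimated correlation). Of 9 metallothionein and zinc genes, SLC30A2 rose at least 1.48-fold and SLC39A4 at least 1.30-fold, both undetected without doxycycline, and MT1X (1.16), detected there on 1 of the 3 arrays, rose, 4 adjusted over the list alone, with a median of 0.31 (adjusted p = 0.167 with an estimated correlation). Of 12 LRH-1 target genes from the literature, APOM (0.52) rose and the bile acid transporter SLC10A1 (-1.35) and cyclin E, CCNE1 (-0.43), fell, also 1 and 2 adjusted over the list alone. That list's median was 0.00 (camera adjusted p = 0.970).

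The count of 1445 fell to 781 without replicate 3 of this line without doxycycline, and to 922 and 789 without replicates 1 and 2 with doxycycline. Of the mitosis genes, 0 passed in limma's test without that replicate 3, 2 without replicate 2 without doxycycline, and 1 and 3 without replicates 1 and 2 with it, against 16 at an unadjusted p under 0.05 with all arrays, although the list's median stayed between -0.30 and -0.23 and its camera call held. Single arrays of this line also moved other list counts, given here without replicate 3 without doxycycline and without replicates 1 and 2 with it: 7, 6 and 6 for the 12 DNA replication genes, and 2, 4 and 3 for the 7 ATF4 target genes, which were 4 without replicate 1 without doxycycline. The 5 NF-kB genes became 3 without replicates 1 or 2 without doxycycline or replicate 2 with it, the 5 Wnt genes 3 without replicate 3 without doxycycline, and the 3 metallothionein and zinc genes 1 without replicate 1 without doxycycline. The call of INSIG1 was lost without replicate 3 without doxycycline or replicates 1 or 2 with it, while 8 cholesterol genes fell without replicate 3 with it. The call of CDH2 was lost without any array of this line except replicate 1 with doxycycline. The NF-kB list's camera call was lost without replicate 2 without doxycycline, and its median of 0.18 became 0.07 without replicate 3 with it. The Wnt median of -0.11 became -0.19 and -0.07 without replicates 2 and 3 without doxycycline, the matrix median of 0.38 became 0.24 without replicate 2 with it and the metallothionein median of 0.31 became 0.18 without replicate 1 with it. The Wnt list's camera call was lost with median scaling, with the replicate number as a block, and without replicate 3 without doxycycline, replicates 1 or 3 with it, or, in the control line, replicate 3 without or replicates 1 or 2 with doxycycline.

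The same treatment of the control line measured what doxycycline did with no LRH-1 hairpin in the label. DDIT4, an inhibitor of mTORC1 signalling, fell by 2.72 on the log2 scale (SE 0.13, adjusted p = 2.70e-06), and ASNS fell by 2.46 (SE 0.14, adjusted p = 3.23e-06). MIR614 rose by 2.39 (SE 0.43, adjusted p = 0.00361) and was detected on 1 of the 3 arrays without doxycycline. In all, 2009 genes changed, 990 higher and 1019 lower, 286 of them at least 2-fold.

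The calcium-binding protein gene TESC rose by 1.91 on the log2 scale, HHLA2, an immune ligand, by 1.86, ERICH4 by 1.84, the small GTPase RRAS by 1.81 and SLC6A20 by 1.93. Undetected without doxycycline, the receptor AMHR2 was at least 3.65-fold higher, KRT16P2 at least 3.34-fold, the cytokine LTB at least 2.47-fold and S100A3 at least 2.38-fold. HHLA2 was detected on 2 of the 3 arrays without doxycycline. SNAR-A1, a small noncoding RNA, fell by 2.42, the NKG2D ligand ULBP1 by 2.41, trypsinogen, PRSS1, by 2.34 and LGALS14 by 2.20. UTS2 fell by 1.99, SCARNA23 by 1.92 and ARRDC4 by 1.92, and LECT2 fell at least 1.88-fold, undetected with doxycycline. ULBP1 was detected with doxycycline on 1 of the 3 arrays.

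Mitosis and DNA replication genes fell broadly in the control line. The list of 21 G1/S regulators was not called (camera adjusted p = 0.180), with 6 lower and 1 higher. Of 31 mitosis genes, 28 fell, 30 adjusted over the list alone, including TPX2, CENPE (-0.88) and CENPF (-0.93), with a median of -0.74 (camera adjusted p = 4.80e-21, adjusted p = 0.0611 with an estimated correlation). Of 30 DNA replication genes, 25 fell, among them CDC45 (-1.22), GINS2 (-1.20) and UHRF1 (-1.10), and GINS1 (0.66), chosen after its value was seen and detected on 2 of the 3 arrays without doxycycline, rose, against 28 and 1 adjusted over the list alone. Their median was -0.66 (camera adjusted p = 1.54e-18, adjusted p = 0.0611 with an estimated correlation). Of 32 integrated stress response and ATF4 target genes, 18 fell, against 22 lower and 1 higher adjusted over the list alone, led by DDIT4, ASNS and the serine synthesis enzyme PSAT1 (-1.74), with a median of -0.51 (camera adjusted p = 8.56e-12, adjusted p = 0.0611 with an estimated correlation). Of 17 Wnt target genes, 7 fell, against 9 lower and 1 higher adjusted over the list alone, including ASCL2 (-1.02), NKD1 (-1.49) and AXIN2 (-0.75), with a median of -0.54 (adjusted p = 0.0721 with an estimated correlation).

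Some genes of absorptive cells and of the interferon response rose in the control line. Of 22 enterocyte genes, 7 rose, also 7 adjusted over the list alone, including the peptide receptor VIPR1 (1.41), CEACAM1 (0.95) and lactase, LCT (1.51), with a median of 0.31 (camera adjusted p = 0.000434, adjusted p = 0.0611 with an estimated correlation). Of 21 interferon response genes, 7 rose, including IFIT1 (1.62), MX1 (0.90) and GBP1 (0.88), and OAS3 (-0.64) fell, against 10 and 1 adjusted over the list alone. The median was 0.37 (camera adjusted p = 0.000651, adjusted p = 0.129 with an estimated correlation). Of 6 fibroblast genes, LUM (0.95), PDGFRA (0.75) and PDGFRB (0.62) rose, 4 adjusted over the list alone, with a median of 0.60 (adjusted p = 0.167 with an estimated correlation). SLC30A2 (1.54), MT1F (0.75) and SLC39A4, at least 1.08-fold, undetected without doxycycline and detected on 2 of the 3 arrays with it, rose among 9 metallothionein and zinc genes, also 3 adjusted over the list alone, with a median of 0.20 (adjusted p = 0.198 with an estimated correlation). CCL20 (0.85), NFKBIE (0.50) and PTGS2 (0.67) rose among 16 NF-kB genes, 5 adjusted over the list alone, with a median of 0.20 (adjusted p = 0.167 with an estimated correlation). CYP3A5 (0.90), UGT1A6 (0.54) and CYP2S1 (0.43) rose among 17 xenobiotic genes, also 3 adjusted over the list alone, with a median of 0.24 (adjusted p = 0.167 with an estimated correlation). Of the 12 LRH-1 target genes, CCNE1 (-0.59) fell, also 1 adjusted over the list alone, with 2 higher there, and the list was not called (camera adjusted p = 0.765). The count of 2009 fell to 1188 without replicate 1 without doxycycline and to 1265 without replicate 3 with doxycycline. The 7 interferon genes became 4 without replicate 1 without doxycycline or replicate 2 with it, and the 3 NF-kB genes became 1 without replicate 1 without doxycycline or replicate 3 with it. The call of GINS1 held only without replicate 3 without doxycycline, replicate 2 with it or replicate 1 of the shRNA-labelled line with it. Without replicate 3 without doxycycline the camera calls of the fibroblast, metallothionein, NF-kB and xenobiotic lists were lost. Without replicate 2 with doxycycline those of the last 3 were lost, and without replicate 1 with it those of the fibroblast and xenobiotic lists. The NF-kB call was also lost without replicate 1 without doxycycline, replicate 3 with it or replicate 1 of the shRNA-labelled line without it, and the xenobiotic call without replicate 2 without doxycycline or any array of the shRNA-labelled line without it. The xenobiotic call was lost too with the authors' values, with no background correction, with normexp and with the replicate number as a block. The Wnt median of -0.54 became -0.34 without replicate 2 without doxycycline and -0.36 without replicate 1 with it, and the metallothionein median of 0.20 became 0.29 without replicate 1 without doxycycline, and 0.10 and 0.34 without replicates 2 and 3 with it.

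The responses of both lines were then compared across genes. Of the genes called in each line, 410 rose in both, against 64.2 from independent lists (odds ratio 19.5, Fisher's exact test p = 1.81e-258), and 258 fell in both, against 51.1 (odds ratio 10.2, Fisher's exact test p = 2.49e-123). S100A3, SLC6A20, PLAUR and TESC rose in both lines, and G0S2, TUBB1, UTS2 and BFSP1 fell in both. These comparisons share no arrays, but they share each gene's estimate of the spread, and genes are not independent. The counts expected from independent lists and Fisher's p-values are therefore only a rough guide. The 668 shared genes became 315 with median scaling, 438 in fits of the compared groups alone, 429 without replicate 3 of the shRNA-labelled line without doxycycline, 380 with a fold limit of 1.5 and 1096 with array weights. Across the 12566 genes the log2 fold changes correlated with Pearson's r = 0.51 and Spearman's rho = 0.43, genes not being independent replicates. Of 2766 genes called in either line, 83.7% had the same sign in both.

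**Figure D2:**
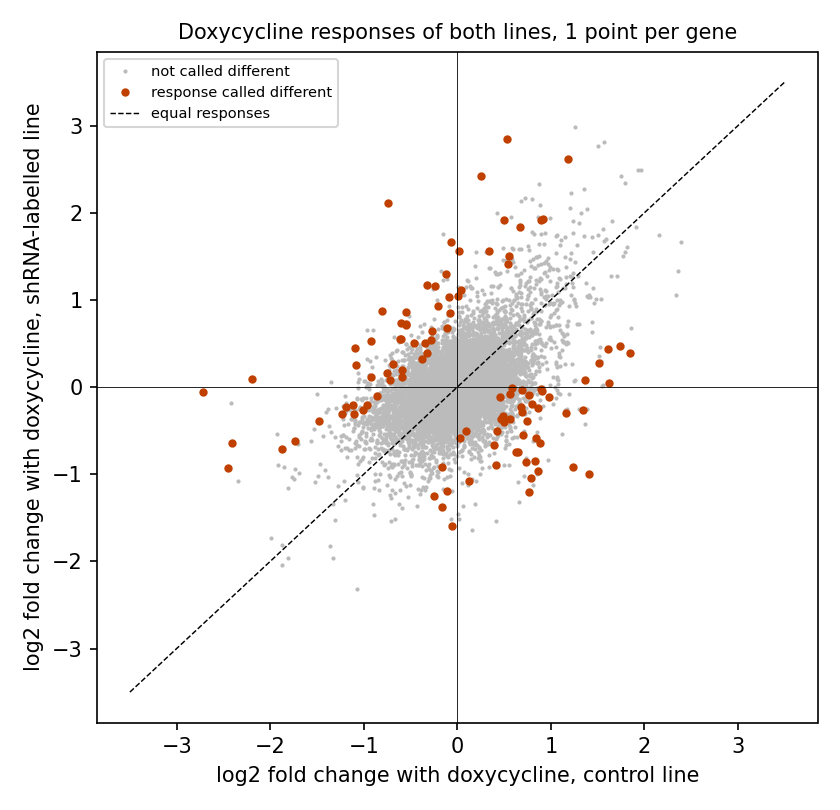
Log2 fold change with doxycycline in the control line (horizontal) against the shRNA-labelled line (vertical), with a point per gene for 12566 genes, the dashed line marking equal responses. The 106 genes whose response was called different, in red, lie away from the dashed line, DDIT4 at -2.72 and -0.05.

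The difference of responses asked which genes answered doxycycline differently in the shRNA-labelled line. DDIT4 had the smallest adjusted p: its fall of 2.72 in the control line met a change of -0.05 in the shRNA-labelled line, a difference of 2.66 (log2, SE 0.19, adjusted p = 0.000159). CEACAM5 differed by 2.32 (SE 0.35, adjusted p = 0.0178). STC1, stanniocalcin, differed by -2.40 (SE 0.47, adjusted p = 0.0448). In all, 106 genes differed, 58 with a higher and 48 with a lower response in the shRNA-labelled line, against 1999 at an unadjusted p under 0.05. The direction of the majority depended on the processing, with 27 higher and 30 lower under median scaling and 20 higher and 23 lower with no filter on detection.

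Further differences above 0 were found for LGALS14 (2.29), ULBP1 (1.77), MIR155HG (1.68) and NUP62CL (1.54). Differences below 0 included genes of liver-type plasma proteins, hemopexin, HPX (-1.96), and FGL1 (-1.60), and of metabolism, LDHD (-2.15), GSTA5 (-1.82), the tryptophan-degrading enzyme TDO2 (-1.68) and CYP4X1 (-1.54). TMEM86B (-1.59) and the interferon-induced IFIT1 (-1.57) were also among the 10. The homeobox gene HOXB8, ACTG2, LY6G6D and the kinase gene MATK were called above 0 and afamin, AFM, below 0, but each was undetected on every array of at least 1 group, so no size is given. HOXB8 and LY6G6D were undetected in the shRNA-labelled line without doxycycline, ACTG2 in both lines without it, AFM in the shRNA-labelled line with it and MATK on every array of the control line. In the shRNA-labelled line with doxycycline, STC1 and LDHD were each detected on 2 of the 3 arrays, and in the control line ULBP1 was detected on 1 of the 3 with it.

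By camera's test the mitosis, DNA replication and stress response lists fell less in the shRNA-labelled line than in the control line, and the cholesterol and hepatocyte lists responded lower, calls that were lost with an estimated correlation (adjusted p = 0.0611 to 0.289), while few or no single members passed. Of 32 stress response and ATF4 target genes, DDIT4, ASNS (1.52), PSAT1 (1.12) and SLC7A1 (0.91) had a higher response, against 13 higher and 1 lower adjusted over the list alone. Leaving out any single array except replicate 3 of either line without doxycycline, replicate 2 of the control line with it or replicate 3 of the shRNA-labelled line with it left 2 of the 4. The median difference was 0.41 (camera adjusted p = 1.18e-07, adjusted p = 0.0611 with an estimated correlation). For 31 mitosis genes the median difference was 0.47 (camera adjusted p = 2.68e-12, adjusted p = 0.0721 with an estimated correlation). In limma's test 0 of them passed over all genes, 20 were higher adjusted over the list alone and 21 at an unadjusted p under 0.05. DLGAP5 differed by 0.88 (adjusted p = 0.0562) and HMMR by 0.68 (adjusted p = 0.0895). For 30 DNA replication genes the median was 0.36 (camera adjusted p = 4.42e-07, adjusted p = 0.167 with an estimated correlation). Of these, 0 passed in limma's test over all genes, 3 were higher adjusted over the list alone and 13 at an unadjusted p under 0.05. Of 19 cholesterol synthesis genes, MSMO1 (-0.83) and SC5D (-0.59) responded lower, 8 adjusted over the list alone, with a median of -0.46 (camera adjusted p = 1.80e-06, adjusted p = 0.0784 with an estimated correlation). In limma's test 0 of them passed without any single array except replicate 3 of the shRNA-labelled line with doxycycline, against 9 at an unadjusted p under 0.05 with all arrays. Of 14 hepatocyte genes, APOH (-1.20) responded lower, 4 adjusted over the list alone, with a median of -0.49 (camera adjusted p = 7.93e-05, adjusted p = 0.289 with an estimated correlation). Of 17 Wnt target genes, CD44 (1.40) responded higher, against 5 higher and 1 lower adjusted over the list alone, with a median of 0.23 (adjusted p = 0.129 with an estimated correlation), and CD44 was no longer called without any single array except replicate 3 of the control line without doxycycline, its replicate 2 with it or replicate 3 of the shRNA-labelled line with it. For 12 LRH-1 target genes the median difference was 0.02 (camera adjusted p = 0.862), with 0 calls in limma's test over all genes 1 lower adjusted over the list alone, and 1 higher and 1 lower at an unadjusted p under 0.05.

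The count of 106 was fragile. Leaving out replicates 1 and 2 of the control line without doxycycline gave 29 and 23 genes, replicates 1 and 3 of the control line with doxycycline 27 and 15, replicates 1, 2 and 3 of the shRNA-labelled line without doxycycline 19, 29 and 20, and its replicates 1, 2 and 3 with doxycycline 18, 23 and 206. Lower responses outnumbered higher ones in each of these, for example 4 higher and 11 lower without replicate 3 of the control line with doxycycline, and 94 higher and 112 lower without replicate 3 of the shRNA-labelled line with it.

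**Figure D3:**
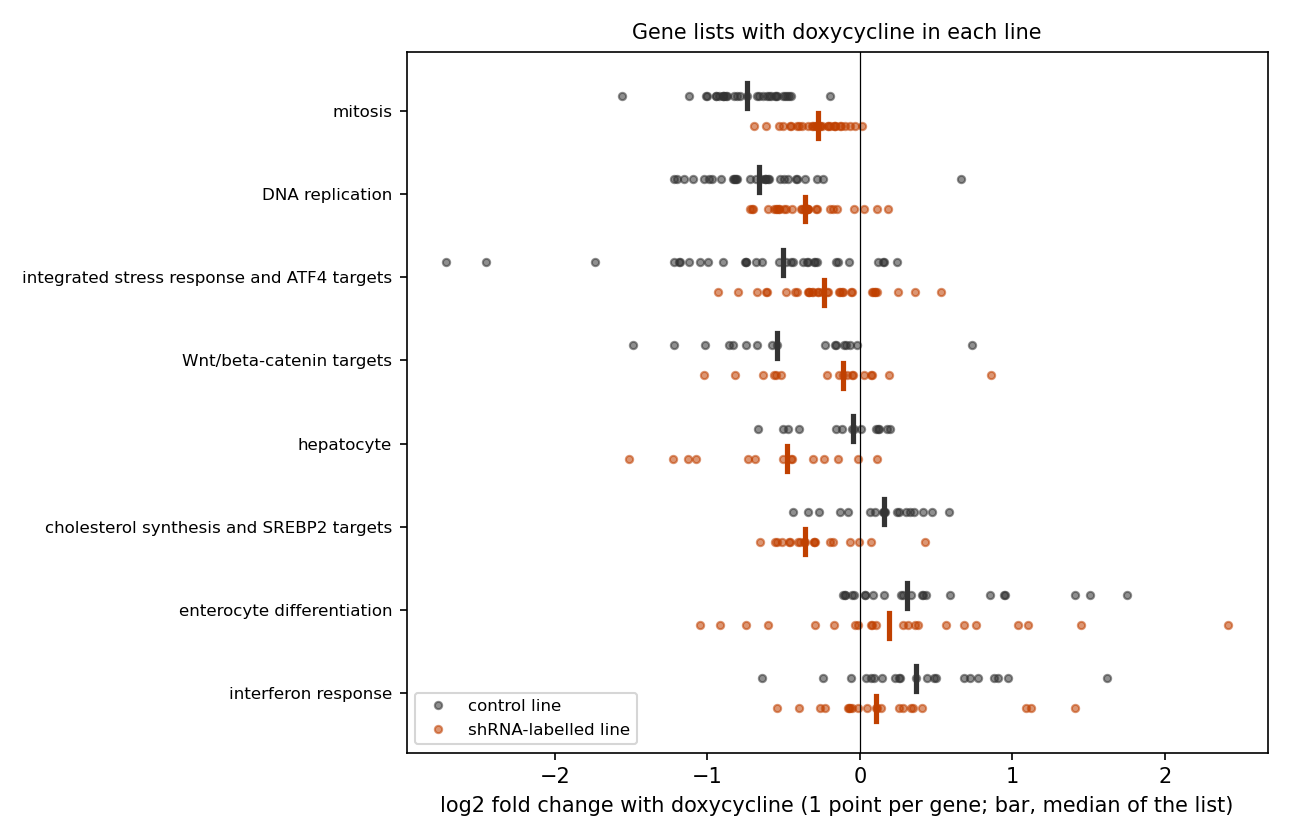
Log2 fold changes with doxycycline of the members of 8 gene lists in the control line (grey) and the shRNA-labelled line (red), with a point per gene and a bar at each list's median. Mitosis genes have medians of -0.74 and -0.28, and stress response and ATF4 target genes of -0.51 and -0.23.

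With doxycycline in both, the lines were set against each other, a comparison that also holds any lasting difference between the lines. By camera's test the mitosis and DNA replication lists were higher in the shRNA-labelled line and the interferon, hepatocyte, endoplasmic reticulum chaperone and NRF2 target lists lower, calls that were lost with an estimated correlation (adjusted p = 0.0611 to 0.350). SNAR-A1 was 25.7-fold higher (log2 4.68, SE 0.40, adjusted p = 1.38e-05) and LGALS14 was 17.7-fold higher (log2 4.14, SE 0.28). SERPINA5, a serine protease inhibitor of plasma, was lower, with a log2 difference of -4.32 (SE 0.32, adjusted p = 5.27e-06). In all, 2846 genes differed, 1365 higher and 1481 lower, 560 of them at least 2-fold.

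The water channel gene AQP10 was 3.76 higher on the log2 scale, the ubiquitin-conjugating enzyme gene UBE2E3 2.90 and OCIAD2 2.78. ADGRL2 was at least 4.43-fold higher, undetected in the control line with doxycycline. STC1 (-3.65), ATP10B (-3.56) and HPX (-3.35) were lower. The complement protease gene C1S was at least 7.51-fold lower and the transporter gene SLC38A4 at least 7.15-fold lower, both undetected in the shRNA-labelled line with doxycycline, where SERPINA5 and STC1 were detected on 2 of the 3 arrays. Of 31 mitosis genes, 29 were higher, 31 adjusted over the list alone, including KIF11 (0.99), BIRC5 (0.95) and TOP2A (0.76), with a median of 0.70 (camera adjusted p = 6.71e-18, adjusted p = 0.0611 with an estimated correlation). Of 30 DNA replication genes, 21 were higher, 26 adjusted over the list alone, with MCM10 (1.04), GINS3 (0.82) and POLE2 (0.82) first and a median of 0.50 (adjusted p = 0.0832 with an estimated correlation). Of 24 glycolysis and hypoxia genes, 10 were higher, with ANKRD37 (1.27) and HK2 (1.00) first, and ADM (-0.72) was lower, the same counts adjusted over the list alone, with a median of 0.31 (adjusted p = 0.289 with an estimated correlation).

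Of 21 interferon response genes, 9 were lower, 10 adjusted over the list alone, led by MX1 (-1.52) and IFIT1 (-2.26), with a median of -0.59 (adjusted p = 0.0832 with an estimated correlation). Of 19 endoplasmic reticulum chaperone genes, 11 were lower, 13 adjusted over the list alone, led by SEL1L (-0.52) and DNAJC3 (-0.72), with a median of -0.45 (adjusted p = 0.0611 with an estimated correlation). The 11 became 7 without replicate 1 or 3 of the control line or replicate 1 of the shRNA-labelled line with doxycycline. Of 17 NRF2 target genes, 9 were lower, 10 adjusted over the list alone, led by the aldo-keto reductases AKR1C2 (-2.49) and AKR1C3 (-1.41), with a median of -0.39 (adjusted p = 0.0721 with an estimated correlation). Both reductases also belong to the 9 steroid synthesis genes, of which 4 were lower and HSD11B2 (0.70) was higher, the same counts adjusted over the list alone, with HSD3B1 (-1.59) and a median of -0.27 (adjusted p = 0.198 with an estimated correlation). Of 14 hepatocyte genes, 7 were lower, 8 adjusted over the list alone, led by APOH (-1.31) and RBP4 (-1.05), with a median of -0.63 (adjusted p = 0.350 with an estimated correlation), which became -0.38 without replicate 2 of the shRNA-labelled line. The steroid median became -0.44 and -0.18 without replicates 2 and 3 of the control line. Of the 12 LRH-1 target genes, 2 were higher and 6 lower, the same counts adjusted over the list alone, with CCNE1 (1.13), MYC (0.75) and the bile pump gene ABCC3 (-0.90) having the smallest adjusted p, and the list was not called (camera adjusted p = 0.241).

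Without doxycycline the lines already differed. RIPOR2 was 10.8-fold lower in the shRNA-labelled line (log2 -3.43, SE 0.17, adjusted p = 8.30e-07), and CEACAM5 was lower by a log2 difference of -2.53 (SE 0.25). ZNF20, a zinc finger gene, was at least 4.15-fold higher, undetected in the control line. By camera's test the stress response, NRF2 target and interferon lists were lower and the mitosis list higher in the shRNA-labelled line, calls that were lost with an estimated correlation (adjusted p = 0.0611 to 0.167). In all, 2052 genes differed, 938 higher and 1114 lower, 328 of them at least 2-fold.

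OCIAD2 was 2.66 higher on the log2 scale, NREP 2.48 and SNAR-A1 2.45, while ADGRL2 was at least 4.25-fold and the neuronal calcium sensor gene VSNL1 at least 3.10-fold higher, both undetected in the control line. SERPINA5 was lower by a log2 difference of -3.31, and MMP10 at least 6.25-fold, the steroid-conjugating enzyme gene UGT2B15 at least 5.20-fold and UNC13C at least 4.27-fold lower, all undetected in the shRNA-labelled line. Of 32 stress response and ATF4 target genes, 16 were lower and 1 higher, 17 and 1 adjusted over the list alone, led by SLC7A11 (-1.25, detected on 2 of the 3 arrays of the shRNA-labelled line), PCK2 (-0.62) and ASNS (-0.72), with a median of -0.36 (adjusted p = 0.129 with an estimated correlation). Of 17 NRF2 target genes, 9 were lower, also 9 adjusted over the list alone, led by AKR1C2 (-1.58) and AKR1C3 (-0.94), with a median of -0.41 (adjusted p = 0.0611 with an estimated correlation). Of 21 interferon genes, 10 were lower, led by IRF9 (-0.86) and IFI6 (-0.94), and TAP1 (0.60) was higher, against 11 and 1 adjusted over the list alone, with a median of -0.44 (adjusted p = 0.155 with an estimated correlation). Of 31 mitosis genes, 8 were higher, 14 adjusted over the list alone, led by KIF11 (0.58) and BIRC5 (0.58), with a median of 0.28 (adjusted p = 0.167 with an estimated correlation). Of 17 Wnt target genes, 6 were lower, led by PROX1 (-1.72) and ASCL2 (-0.52), and MYC (0.46) was higher, the same counts adjusted over the list alone, with a median of -0.27 (adjusted p = 0.219 with an estimated correlation). Of the 12 LRH-1 target genes, 2 were higher and 5 lower, the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.399). The count of 2052 fell to 1136 without replicate 1 of the control line without doxycycline and to 1249 and 1303 without replicates 1 and 3 of the shRNA-labelled line without it. Without these 3 arrays in turn, the 16 lower ATF4 target genes became 8, 10 and 10, the 10 lower interferon genes 6, 4 and 4, and the 8 higher mitosis genes 3, 5 and 3. Without replicate 2 of the control line the interferon and mitosis counts were 4 and 5, and without replicate 2 of the shRNA-labelled line the Wnt list's camera call was lost, as it was with median scaling, while its median became -0.17 without replicate 1 of the control line.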

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

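The tests of exchanged labels, of a masked silencing, of levels before doxycycline, and of gene lists without single arrays or with median scaling were chosen after the results were seen, while the tests of the difference of responses and of other splits were not. The response to doxycycline differed between the lines, by limma's test of the difference itself, for 106 genes. Of 100 splits drawn within each line, after the additive effects of line and doxycycline were removed, 1, the real one, gave as many genes. The highest of the others gave 5, and 0.01 is the smallest share that this number of splits allows. The difference of responses itself was not removed and widens the spread within the other splits, which lowers their counts. These splits therefore do not exclude chance as a source of this count. Called in opposite directions in the lines were 20 genes, among them TDO2, F10 and GSTA5, lower with doxycycline in the shRNA-labelled line and higher in the control line (chosen after their values were seen). By camera's test of the difference, 6 gene lists also responded differently, with median differences of 0.47 for mitosis, 0.41 for ATF4 targets, 0.36 for DNA replication, 0.23 for Wnt targets, -0.46 for cholesterol synthesis and -0.49 for hepatocyte genes. None of these list calls held with an estimated correlation.

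NR5A2 was higher, not lower, with doxycycline in the shRNA-labelled line. An exchange of the doxycycline labels in that line alone would turn the shared response round, but 84.7% of the genes called in the control line had the same sign there. An exchange in both lines would leave this share unchanged, so the share cannot decide on that case. An exchange of the line labels would make NR5A2 fall in the control line if silencing outweighed any shared rise, but it rose there by 0.89. If a shared rise masked silencing, this value could not decide on such an exchange. A rise that both lines share may mask silencing: the difference of responses was -0.39 on the brighter probe but -0.09 on the other, which leaves this open. No protein was measured here, and which parts of the transcript the probes match is not analysed here.

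By camera's test the ATF4 target list fell more with doxycycline in the control line than in the shRNA-labelled line. The call was lost with an estimated correlation (adjusted p = 0.0611), and 4 of 32 members passed singly for the difference of responses. Leaving out any single array kept the median difference at 0.33 or more, and median scaling kept it at 0.25, which argues against an effect of a single array or of quantile normalization as the whole cause. The lines already differed without doxycycline, by a median of -0.36 (-0.22 with median scaling), and not by a called amount with it, at 0.06. Members went beyond a meeting of the lines, though: with doxycycline 6 of 32 were higher in the shRNA-labelled line and 2 lower, and DDIT4 went from -0.61 without doxycycline to 2.06 with it and ASNS from -0.72 to 0.80. Whether the difference reflects where each line started therefore stays open, beside an effect of the hairpin.

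By camera's test the mitosis list likewise fell more in the control line, although 0 of its 31 members passed singly for the difference of responses. The leave-one-out median closest to 0 was 0.41, and median scaling gave 0.39. Read by the same rule, settled for both lists after their values were seen, the lines did not meet with doxycycline. They differed by 0.28 without it and by 0.70 with it. Because the start and the difference of responses had the same sign, a wider gap with doxycycline had to follow. The rule therefore cannot decide whether the start of the lines accounts for this pattern. Because the lines were already apart in the same direction, a lasting line difference in growth stays open beside an effect of the hairpin, and the list's call was lost with an estimated correlation.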

How the results depend on the processing

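The list medians, counts and calls with no background correction, normexp or median scaling and without single arrays were chosen after seeing the data. Of 259 results for named genes and list members, median scaling changed 48 to no longer called and single arrays changed 3 to 32 (32 without replicate 3 of the shRNA-labelled line without doxycycline), while no named gene or list call changed direction under the alternatives it was run under. The majority direction of the genes called did turn in places: in the shRNA-labelled line (815 higher, 630 lower) with median scaling (384 and 403) and array weights (1288 and 1410), and for the difference of responses (58 and 48) with median scaling (27 and 30), with no filter on detection (20 and 23) and without 10 of the 12 arrays. In the control line (990 and 1019) it turned with the mean of all probes (1026 and 1006) and without 2 arrays, and between the lines with doxycycline (1365 and 1481) without 1 array (1204 and 1149). Median scaling instead of quantile normalization gave 787 genes for doxycycline in the shRNA-labelled line, 1027 in the control line, 57 for the difference of responses, 1670 and 984 between the lines with and without doxycycline, 315 genes shared by both responses, and a rise of NR5A2 of 0.40. Fitting only the groups compared gave 958 genes in the shRNA-labelled line and 438 shared. Array weights gave 2698 genes in the shRNA-labelled line, 527 for the difference, 3370 between the lines without doxycycline and 1096 shared. Requiring a fold of at least 1.5 gave 882, 1117, 1640 and 1125 genes for the shRNA-labelled line, the control line and the lines with and without doxycycline, and 380 shared. The difference of responses also gave 318 genes with no background correction, 207 with normexp, 43 with no filter on detection, 211 with a stricter filter and 299 with trended robust variance. For the fold limit, the smaller counts follow from its construction, and otherwise the cause was not tested. Leaving out single arrays gave 781 to 1547 genes in the shRNA-labelled line, 1188 to 2091 in the control line, 15 to 206 for the difference, 2099 to 2912 and 1136 to 2165 between the lines with and without doxycycline, 429 to 652 shared genes (429 without replicate 3 of the shRNA-labelled line without doxycycline), and a rise of NR5A2 of 0.42 to 0.55. Same-numbered replicates deviated together weakly at most (correlations of -0.19 to 0.23, with 7 of 12 arrays closest to an array of their own number). Whether 7 is more than unpaired numbers would give was not tested, so a weak pairing is not ruled out. With the replicate number as a block the counts were 1345, 1946, 84, 2834 and 1970 genes, 618 were shared and NR5A2 rose by 0.50. Of 45 list calls, the block ended 2 (Wnt in the shRNA-labelled line, xenobiotic in the control line), the authors' values, no background correction and normexp the xenobiotic call each, fry 1 (glycolysis between the lines without doxycycline), median scaling 3 (Wnt in the shRNA-labelled line, and Wnt and chaperones between the lines without doxycycline) and an estimated correlation all 45. With no background correction 16 list medians shrank by more than 1.5 times. With median scaling 2 shrank by as much, ATF4 targets for the difference of responses (0.41 to 0.25) and between the lines without doxycycline (-0.36 to -0.22), and 3 grew, Wnt in the shRNA-labelled line (-0.11 to -0.21), hepatocyte genes for the difference (-0.49 to -0.75) and glycolysis between the lines without doxycycline (0.18 to 0.29). The Wnt call in the shRNA-labelled line and the xenobiotic call in the control line were the least stable, lost without 6 and 7 of the 12 arrays. For the 4 comparisons of 3 against 3 arrays, 10 splits are too few for a share under 0.05. The real splits, 1 of 10 each, gave 958, 1569, 2323 and 1640 genes in fits of 6 arrays, and the highest of the others gave 0. Signal over background limits dim genes. Folds are bounds only for genes undetected on every array of a group. Genes detected on only some arrays of a group have plain values, whose size is uncertain.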

Other observations

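The test of ATF4 target induction, and the list counts and calls with median scaling and without single arrays, were chosen after the results were seen, while the gene lists and comparisons were not. Several fixed lists without a call held single genes that moved with doxycycline in the shRNA-labelled line. Of 22 enterocyte genes, 5 rose and 3 fell, 6 and 4 adjusted over the list alone: CEACAM1 (1.45), VIPR1 (1.04), MUC13 (1.10) and KRT20 (2.42, detected on 2 of the 3 arrays without doxycycline) rose, and the apolipoprotein gene APOC3 (-1.05) fell. Of 17 p53 target genes, 4 rose and 1 fell, 5 and 2 adjusted over the list alone, with PHLDA3 (1.33, detected on 1 of the 3 arrays without doxycycline) and the cyclin-dependent kinase inhibitor CDKN1A (0.70) having the smallest adjusted p. Of 21 G1/S regulators, 2 rose and 4 fell, the same counts adjusted over the list alone, E2F2 (-0.72) and CDC25A (-0.59) first. CDKN1A (1.17), E2F2 (-0.99) and CDC25A (-0.79) also changed in the control line. In the difference of responses, 3 of 21 interferon genes responded lower in the shRNA-labelled line, IFIT1 (-1.57), MX1 (-0.95) and TAP1 (-0.90), against 3 lower and 1 higher adjusted over the list alone, and the list was not called (camera adjusted p = 0.0743).

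Further lists were called between the lines without doxycycline, and none of these calls held with an estimated correlation (adjusted p = 0.129 to 0.465). Higher in the shRNA-labelled line were 9 of 30 DNA replication genes, also 9 adjusted over the list alone (GINS4 at least 1.29-fold, undetected in the control line, RRM2 0.94 and CDT1 0.59, list median 0.17), and 3 of 19 cholesterol synthesis genes, also 3 (MSMO1 0.59, SC5D 0.38, NSDHL 0.41, median 0.32). Also higher were 6 of 30 mitochondrial ribosome genes, 7 adjusted over the list alone (MRPL44 0.55, MRPL19 0.53, median 0.13), and 5 of 24 glycolysis and hypoxia genes, against 7 higher and 1 lower (ALDOC 0.98, ANKRD37 0.63, median 0.18). Lower were 7 of 19 endoplasmic reticulum chaperone genes, 8 adjusted over the list alone (SEL1L -0.63, CALR -0.66, median -0.21), and 4 of 9 steroid synthesis genes, also 4 (AKR1C2 -1.58, AKR1C3 -0.94, HSD3B1 -0.60, HSD17B2 -0.44, median -0.28). Without replicate 1 of the control line without doxycycline, the DNA replication count was 4, the mitochondrial ribosome count 2, the glycolysis count 1 and the chaperone count 4. Without replicate 3 of that group, DNA replication and mitochondrial ribosome counts were 5 and 2, and without replicates 1 and 3 of the shRNA-labelled line without doxycycline 5 and 3, and 4 and 2. Without replicate 2 of that line without doxycycline the glycolysis and chaperone counts were 3 and 4, and without replicate 3 of the control line with doxycycline the mitochondrial ribosome count was 3. The chaperone call was lost with median scaling. The glycolysis call was lost with fry and without 5 arrays, replicates 1 and 3 of the control line without and with doxycycline and replicate 2 of the shRNA-labelled line without it, and the mitochondrial ribosome call without replicate 3 of the control line without it. The glycolysis median of 0.18 became 0.11 without replicate 2 of the shRNA-labelled line without doxycycline.

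Doxycycline blocks mitochondrial translation, which is known to induce ATF4 targets in many cells, so a rise of these genes in both lines was a possible outcome. The opposite was measured: the higher of the medians in the lines was -0.23, in the shRNA-labelled line, and the control line's was -0.51. Both calls of a fall were lost with an estimated correlation (adjusted p = 0.198 in the shRNA-labelled line and 0.0611 in the control line), and the 7 lower genes of the shRNA-labelled line became 2 without its replicate 3 without doxycycline, 4 without its replicate 1 without or with doxycycline and 3 without its replicate 2 with it. The measured medians therefore give no sign of induction of the ATF4 list at 96 hours, while the fall itself is less certain, and earlier times were not analysed here.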
